A study of Mus musculus with 11 samples.

How the data were processed

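RNA was taken from the lumbar spinal cord of C57BL/6 mice at 10 months of age, per the labels, and stranded libraries were made from poly(A) RNA with the TruSeq kit. The labels assign 3 libraries to nontransgenic mice, 3 to MFN2-R94Q and 5 to MFN2-R94Q:MFN1. They name no sex, batch or pairing, and replicate numbers are in the order of the records, so they pair nothing. The design text counts mice, so each library was taken as 1 animal. No 2 libraries of a group were alike enough to be 1 library: the SD of their log2 difference over genes ranged from 0.126 to 0.238.

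The authors deposited RPKM values, 1 column per library, for 20888 gene symbols. Per the submitters' processing notes, TopHat (version not given) and Partek 7.17.0918 were used with the mouse build mm10. The annotation, the rule for reads that match several genes, and whether counting used the strand are not given in the sources used here. Values of overlapping, antisense or near-identical genes are therefore uncertain, and Hbb-b2 and Hbb-bt carry the same values in all 11 libraries. A spreadsheet had turned 25 gene names into dates; these rows were tested but none is named. Genes of the mitochondrial genome were not analysed here.

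RPKM depends on depth and gene length, but the depth could be recovered. For short RNA genes (microRNA and small nucleolar RNA genes under 160 bases in RefSeq on GRCm38.p6), low values are whole multiples of 1 read. Of the values corresponding to at most 5 reads, 91.1% to 95.5% per library lay within 0.02 of a whole number. The depths so obtained were 54.1, 43.6 and 34.7 M reads in nTg replicates 1 to 3, and 30.7, 41.9 and 52.5 M reads in MFN2-R94Q. They were 43.3, 72.0, 36.5, 36.6 and 47.9 M reads in MFN2-R94Q:MFN1. Counting error was not separated from the spread between animals.

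Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend) on log2(RPKM + 0.5), in 1 fit of all 11 libraries with genotype as the only term. Genes with at least 0.5 RPKM in at least 3 libraries were kept, 14347 in all. Tests are two-sided with Benjamini-Hochberg adjustment, and the threshold is an adjusted p of 0.05. Fold changes are on the log2(RPKM + 0.5) scale and understate the change of low genes; errors after RPKM values are SDs. The limma p-values rest on the spread between animals, taken per gene over all 3 groups and so also from the group outside each comparison. That shared spread can differ from the spread of the groups compared. The median absolute log2 deviation of a library from the rest of its group was 0.091, 0.107 and 0.062 in MFN2-R94Q. It was at most 0.059 in every other library.

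Gene lists were 38, fixed before the data were examined with 790 symbols, of which 683 were tested; 37 symbols belong to more than 1 list. The 35 lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01. With that correlation assumed, camera p-values rest on the spread between genes and not on the spread between animals alone. Each list was also tested with an estimated correlation, and with fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes. A list score is the mean difference of its members from the nTg mean.

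The genes named were chosen by a rule set at the same time. Mfn1 and Mfn2 came first. Each comparison then gave the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap and whose higher group averaged at least 1 RPKM. Predicted genes, microRNA and small nucleolar RNA genes and sex-linked genes were left out. Each list past camera, or with a member past the threshold, gave up to 4 members with the smallest p. Some genes that the rule took are not reported here. A gene named in 1 comparison may be given in the others. The retromer partners and neighbours of Vps35 and list members outside this rule were named after their values were seen.

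The limma and camera steps were tested on simulated data that used the real means and spreads, with genes drawn independently, over 14347 genes. Changes of 0.5 on the log2 scale were recovered in 90% of cases for MFN2-R94Q against nTg, 91% for MFN2-R94Q:MFN1 against MFN2-R94Q and 88% for MFN2-R94Q:MFN1 against nTg. Changes of 1 were recovered in 97%, 99% and 99%. Unchanged genes made up 5.56%, 5.94% and 4.59% of the calls.

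Alternatives covered the pseudocount, filter, scaling, design, library weights, thresholds and each library left out in turn. A sex term was planned only if both sexes occurred. All 11 libraries had Ddx3y between 13.9 and 18.0 RPKM and Xist at 0.019 RPKM or less, so it was not fitted. A correction for transcript length and GC content, by loess with a span of 0.5 on the longest GENCODE M21 transcript, was added after the data were seen. It covered 96.6% of the tested genes. The relation between comparisons was set against 50 simulated data sets with genes drawn independently. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.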

Results

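The study measured messenger RNA in the lumbar spinal cord of C57BL/6 mice at 10 months of age by RNA sequencing. Its title places the work in a mouse model of Charcot-Marie-Tooth disease type 2A, an inherited axonal neuropathy caused by mutations of MFN2, one of the mitofusins that fuse mitochondrial outer membranes. The 11 libraries fell into 3 genotype groups: 3 from nontransgenic mice (nTg), 3 from mice with the mutant MFN2-R94Q, and 5 from mice with both MFN2-R94Q and MFN1. Values are the deposited RPKM, reads scaled by gene length and library depth. The depth recovered from the smallest steps of the values ranged from 30.7 to 72.0 M reads per library and overlapped between the groups. In a principal component analysis, MFN2-R94Q replicate 2 lay apart, at 27.0 on the component that held 39.6% of the variance. The other MFN2-R94Q libraries lay at 6.20 and 8.05, and the remaining 8 libraries lay between -8.23 and -2.48.

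Mfn1 (chromosome 3, 32529465 to 32579239, GRCm38) was at 24.9 ± 0.67 RPKM in nTg (SD, n = 3), 26.3 ± 0.42 in MFN2-R94Q (n = 3) and 25.0 ± 0.55 in MFN2-R94Q:MFN1 (n = 5). Mfn2 (chromosome 4, 147873599 to 147904704) was at 45.9 ± 1.2, 46.3 ± 1.4 and 45.2 ± 1.6 RPKM in the same groups. Neither gene passed the limma threshold in any of the 3 comparisons; the smallest adjusted p for Mfn1 was 0.13. Under quantile normalization Mfn1 was past the threshold in MFN2-R94Q against nTg, at a log2 fold change of 0.11, against 0.08 as deposited. The species of the transgenes was not given in the sources used here, so the mouse genes do not check the labels.

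**Figure D1:**
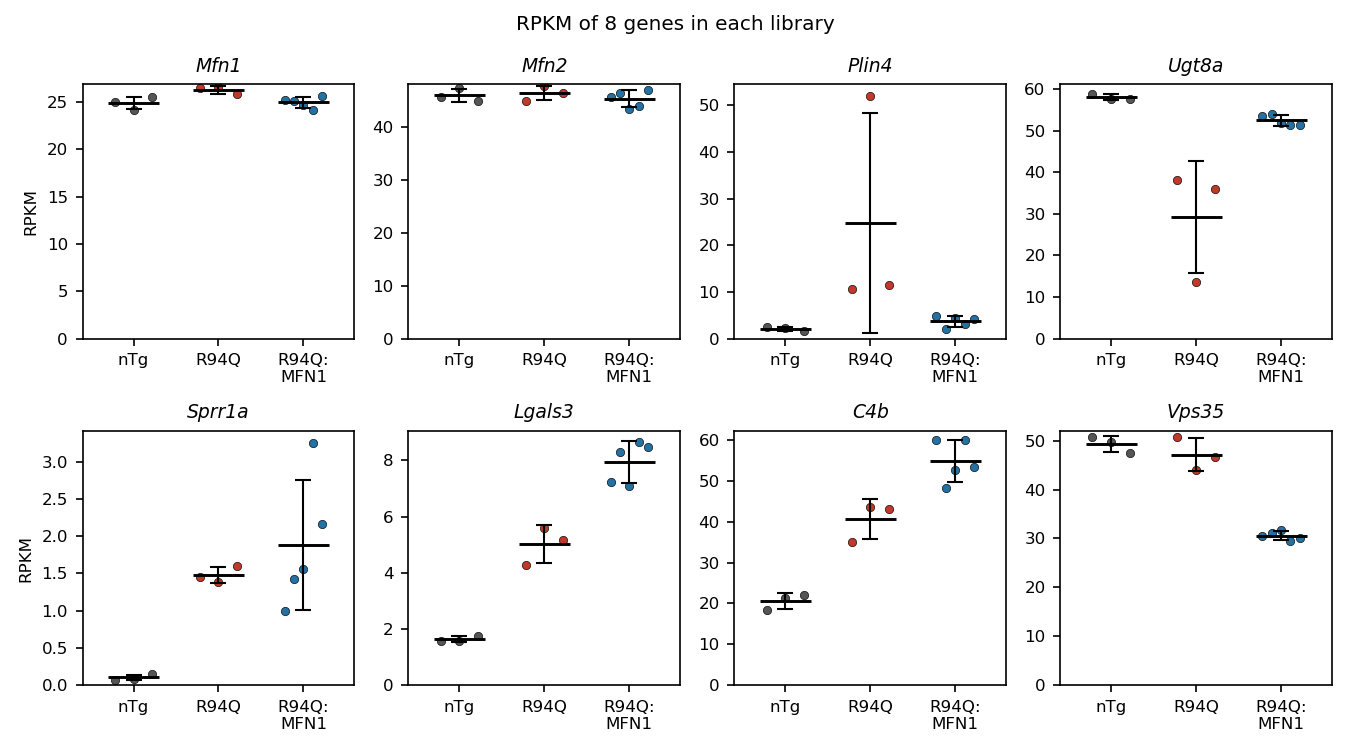
RPKM of Mfn1, Mfn2, Plin4, Ugt8a, Sprr1a, Lgals3, C4b and Vps35 in each library (points), with the group mean and SD (bars), for nTg (n = 3), MFN2-R94Q (n = 3) and MFN2-R94Q:MFN1 (n = 5). Vps35 lies at 30.6 ± 0.92 RPKM in MFN2-R94Q:MFN1 and at 49.3 ± 1.6 in nTg, while Plin4 reaches 51.9 RPKM in a single MFN2-R94Q library.

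The first comparison asked what the mutant mitofusin changed, MFN2-R94Q against nTg. Of the lists fixed for this tissue, 7 of 17 glucocorticoid response, 13 of 33 reactive astrocyte and 12 of 29 disease associated microglia genes rose in MFN2-R94Q spinal cord, and 14 of 28 myelin and 16 of 24 cholesterol synthesis genes fell. These lists passed camera with the preset correlation, and no list did with an estimated correlation (for these, adjusted p = 0.42, 0.38, 0.11, 0.42 and 0.42 with an estimated correlation). With fry their adjusted p was 0.054, 0.0033, 0.00028, 0.027 and 0.017, in the same order. The largest fitted rise was in Plin4, a lipid droplet coat protein gene, from 2.09 ± 0.44 RPKM (SD, n = 3) to 24.7 ± 24, or 7.47-fold (log2 2.90, SE 0.46, adjusted p = 0.0031). Sprr1a, a gene induced in injured neurons, rose a fitted 3.29-fold, to 1.48 ± 0.11 RPKM from 0.101 ± 0.040. At such low levels the fitted value understates the change. By mean RPKM the relative rise of Sprr1a was larger than that of Plin4. Lgals3, which encodes galectin-3 of reactive microglia and macrophages, rose 2.57-fold to 5.01 ± 0.68 RPKM from 1.64 ± 0.094 (adjusted p = 3.4e-05).

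The other leading rises were Gabrr2 (a GABA receptor subunit, 3.46-fold), Sult1a1 (a sulfotransferase, 3.27-fold), Ddc (aromatic amino acid decarboxylase, 3.04-fold), Hif3a (2.88-fold), Cox6a2 (a cytochrome oxidase subunit, 2.40-fold), Ada (adenosine deaminase, 2.23-fold) and Cd109 (2.20-fold). The leading falls were Hspa1b to 0.237 of the nTg level, Nat8f3 to 0.402, Bfsp2 to 0.443, Igfbp2 to 0.448 and Hspa1a to 0.462. Ugt8a, which makes the myelin lipid galactosylceramide, fell to 0.463. Nat8f5, Gng11 and Serpind1 fell to 0.478, 0.486 and 0.492. Hspa1a and Hspa1b are near-identical copies, as are members of the Nat8f family, so the division of reads within each family is uncertain. Without MFN2-R94Q replicate 2 the Plin4 rise was 4.51-fold, Ugt8a fell to 0.641 of the nTg level, Hspa1b and Hspa1a did not pass at 0.308 and 0.509 of that level (adjusted p = 0.055 and 0.086), and Cox6a2 was below the expression filter. Cox6a2 was also lost without any 1 of the nTg libraries, Hspa1b without nTg replicate 1 or 2, and Hspa1a without nTg replicate 1 or 3 or MFN2-R94Q replicate 3.

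Of 17 measured glucocorticoid response genes, 7 rose and none fell, or 16 adjusted over the list alone, with a median log2 fold change of 0.82 (camera adjusted p = 5.2e-07, adjusted p = 0.42 with an estimated correlation). The list did not pass with fry either (adjusted p = 0.054). Fkbp5, a classical glucocorticoid target, rose 1.95-fold, and the metallothionein genes Mt1 and Mt2 rose 1.74-fold and 1.86-fold. The list score was 1.87 in MFN2-R94Q replicate 2, 0.37 in replicate 1 and 0.79 in replicate 3, and was at most 0.26 in every other library. Without replicate 2, 6 members rose, the median was 0.37 and the camera adjusted p was 6.5e-07.

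Of 33 reactive astrocyte genes, 13 rose and none fell (14 adjusted over the list alone, camera adjusted p = 9.3e-07, adjusted p = 0.38 with an estimated correlation). Gfap, the intermediate filament of astrocytes, rose 1.43-fold from 274 ± 16 RPKM, Vim rose 1.72-fold and the complement gene C4b rose 1.94-fold. Of 29 disease associated microglia genes, 12 rose and none fell (14 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.11 with an estimated correlation). They included Lyz2, a lysozyme gene (1.56-fold), Ccl4, a chemokine gene (1.56-fold), and Gpnmb (1.41-fold). The 26 general microglia markers did not pass as a list, with a median of -0.03 that was 0.06 without MFN2-R94Q replicate 2 (3 rose and 3 fell; 4 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.82). In the complement list 4 of 16 members rose and 1, Cd55, fell (11 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.42 with an estimated correlation). The complement rises were 2 without MFN2-R94Q replicate 2 (3 adjusted over the list alone). Of 18 circadian clock genes 7 rose, among them Tef, Cry2, Hlf and Ciart (9 adjusted over the list alone, camera adjusted p = 0.00024, adjusted p = 0.083 with an estimated correlation).

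Of 28 oligodendrocyte and myelin genes, 14 fell and 2 rose (16 fell and 3 rose adjusted over the list alone, camera adjusted p = 0.00024, adjusted p = 0.42 with an estimated correlation). Trf, the transferrin made by oligodendrocytes, fell to 0.576 of the nTg level, Gjb1 to 0.608 and Mag to 0.783, whereas Tspan2 rose 1.21-fold. The myelin score was lowest in MFN2-R94Q replicate 2, at -0.51, against -0.20 and -0.17 in replicates 1 and 3; without replicate 2 the list median moved from -0.25 to -0.15. Of 24 cholesterol synthesis genes, 16 fell and none rose, including Fdft1, Dhcr7 and Msmo1 (17 adjusted over the list alone, camera adjusted p = 3.1e-07, adjusted p = 0.42 with an estimated correlation). Respiratory complex I had 14 of 36 members lower and complexes II to V had 14 of 39, with none higher in either (22 and 23 adjusted over the list alone). Both lists had a camera adjusted p under the threshold, 3.6e-08 and 1.7e-08, and an adjusted p = 0.42 with an estimated correlation. The falls were small: Ndufa3 fell by 0.26 and Uqcrq by 0.30 on the log2 scale. Under quantile normalization 8 and 9 members were lower, at medians of -0.10 each. The respiratory medians went from -0.15 and -0.14 to -0.08 and -0.07 once trends with transcript length and GC content were removed, an alternative chosen after the data were seen.

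Motor neuron markers fell more often than they rose: 7 of 18 were lower and 1, Calca, was higher (10 and 1 adjusted over the list alone, camera adjusted p = 0.0047, adjusted p = 0.42 with an estimated correlation). Prph, Mmp9 and Slc18a3 (the vesicular acetylcholine transporter) fell to 0.852, 0.851 and 0.864 of the nTg level, and Chodl, a marker of fast motor neurons, fell to 0.664. The neurofilament list had 7 of 20 members lower (10 adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.57 with an estimated correlation). Nefh fell to 0.760, Nefl to 0.834 and Ina to 0.875; under quantile normalization, or without MFN2-R94Q replicate 2, this list did not pass (adjusted p = 0.18 and 0.061), at medians of -0.04 and -0.06 against -0.06. Of 14 heat shock genes 8 fell and 1, Hspb8, rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.00055, adjusted p = 0.42 with an estimated correlation), with Cryab at 0.621. Of 30 interferon response genes 7 fell, including Ifitm3, Usp18 and Rsad2 (9 adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.53 with an estimated correlation). Without MFN2-R94Q replicate 2, 2 interferon genes and 5 heat shock genes were lower. Without nTg replicate 3 the interferon call was lost, at a median of -0.15 against -0.20. Of 5 measured sensory ganglion markers 2 fell, Prph and Rgs4 (2 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.42 with an estimated correlation). That call was lost without MFN2-R94Q replicate 2 (adjusted p = 0.051), at a median of -0.13 against -0.16. It was also lost without MFN2-R94Q replicate 3 or nTg replicate 3, at medians of -0.16 and -0.15.

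In all, limma called 2561 of 14347 tested genes, 1076 higher and 1485 lower, but 28 of them by 2-fold or more. Quantile normalization gave 1267 higher and 1278 lower (49.8% higher, against 42.0%), without a lean toward lower. The groups did not overlap for 35.7% of tested genes, where chance gives 10%. The count was 844 when the 2 groups were fitted alone, 1618 without MFN2-R94Q replicate 2, and 1692, 1213 and 1684 without nTg replicates 1, 2 and 3.

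**Figure D2:**
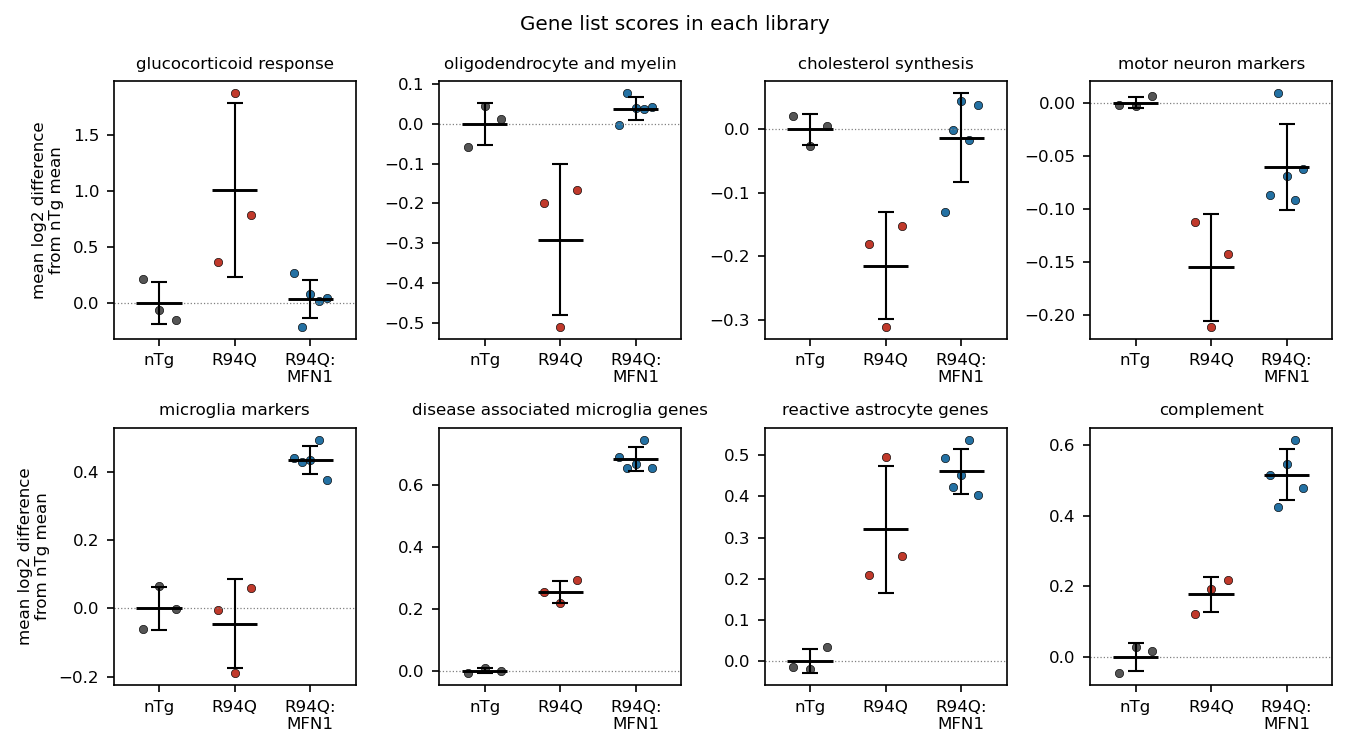
Scores of 8 gene lists in each library, as the mean log2(RPKM + 0.5) difference of the measured members from the nTg mean (points), with group mean and SD (bars), for nTg (n = 3), MFN2-R94Q (n = 3) and MFN2-R94Q:MFN1 (n = 5). The glucocorticoid score reaches 1.87 in a single MFN2-R94Q library, and the disease associated microglia scores of MFN2-R94Q:MFN1 all lie above those of the other groups.

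The second comparison asked what the addition of MFN1 changed on the mutant background, MFN2-R94Q:MFN1 against MFN2-R94Q. With MFN1, 24 of 26 microglia markers, 23 of 29 disease associated microglia genes, 22 of 30 interferon response genes and 17 of 28 myelin genes were higher, and 9 of 17 glucocorticoid response genes were lower. With an estimated correlation the disease associated microglia list passed (adjusted p = 0.0072) and the others did not (adjusted p = 0.12, 0.16, 0.30 and 0.30 with an estimated correlation). Tyrobp, a signalling adaptor of microglia, rose 1.69-fold, to 37.5 ± 0.88 RPKM (SD, n = 5), with a log2 fold change of 0.76 (SE 0.041, adjusted p = 1.8e-06). Plin4 fell to 0.213 of the MFN2-R94Q level, at 3.72 ± 1.2 RPKM with MFN1. Ugt8a rose 1.96-fold, from 29.2 ± 14 to 52.4 ± 1.2 RPKM.

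The other leading rises were Gkn3 (2.76-fold), Cd74 (2.11-fold), Cd52 (2.06-fold), H2-Aa (1.98-fold), Cst7 (1.97-fold), Lyz2 (1.93-fold), Bfsp2 (1.92-fold) and Hist1h4h (1.90-fold). The other leading falls were Cdkn1a to 0.302, Gabrr2 to 0.316, Sult1a1 to 0.349, Hif3a to 0.393, Ddc to 0.397, Ada to 0.522, Pla2g3 to 0.525, Fkbp5 to 0.536 and Rhoj to 0.608 of the MFN2-R94Q level. Without MFN2-R94Q replicate 2, Cd74, H2-Aa and Ada no longer passed (adjusted p = 0.13, 0.098 and 0.062), though Cd74 and H2-Aa were about as high (2.06-fold and 1.97-fold), while Ada was at 0.672 of the MFN2-R94Q level. Ugt8a then rose 1.41-fold, and the falls were to 0.352 for Plin4, 0.465 for Gabrr2, 0.554 for Cdkn1a and Hif3a, 0.572 for Ddc, 0.666 for Pla2g3, 0.737 for Fkbp5 and 0.781 for Rhoj. Cd74 and H2-Aa were lost in 8 of the 11 runs that left out 1 library, Fkbp5 in 4, Rhoj in 3 and Cdkn1a in 2. Histone H4 and antigen presentation genes have close copies, so reads may be divided among them.

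Of 26 microglia markers 24 rose and none fell (26 adjusted over the list alone, camera adjusted p = 7.5e-22, adjusted p = 0.12 with an estimated correlation). Laptm5 rose 1.41-fold and C1qa, a chain of complement C1q, rose 1.53-fold. Of 29 disease associated microglia genes 23 rose, including Gpnmb at 1.58-fold (24 adjusted over the list alone, camera adjusted p = 2.7e-18); this was the 1 list past the threshold with an estimated correlation (adjusted p = 0.0072). The interferon list had 22 of 30 members higher, with Ifitm3 at 1.62-fold and Bst2 at 1.67-fold (25 adjusted over the list alone, camera adjusted p = 9.8e-15, adjusted p = 0.16 with an estimated correlation). The complement list had 11 of 16 higher (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.16 with an estimated correlation). The antigen presentation list had 12 of 22 higher, with B2m at 1.44-fold (16 adjusted over the list alone, camera adjusted p = 3.1e-06, adjusted p = 0.30 with an estimated correlation). Without MFN2-R94Q replicate 2, 4 members of that list passed, and under quantile normalization 7. Reactive astrocyte genes went both ways, 15 higher and 3 lower of 33 (15 and 5 adjusted over the list alone, camera adjusted p = 0.0031, adjusted p = 0.44 with an estimated correlation). That call was lost without MFN2-R94Q replicate 1, at a median of 0.15 against 0.23, and without MFN2-R94Q replicate 2 the lower members were 1.

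Glucocorticoid response genes were lower in 9 of 17 cases (17 adjusted over the list alone, camera adjusted p = 1.9e-10, adjusted p = 0.30 with an estimated correlation), with a median log2 fold change of -0.90 that came to -0.39, with 5 members lower, without MFN2-R94Q replicate 2. Of 28 oligodendrocyte and myelin genes 17 rose and none fell (20 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.2e-06, adjusted p = 0.30 with an estimated correlation), with Trf at 1.71-fold and Mag at 1.29-fold. Of 24 cholesterol synthesis genes 16 rose, including Dhcr7, Pmvk, Fdft1 and Mvd (17 adjusted over the list alone, camera adjusted p = 5.2e-08, adjusted p = 0.30 with an estimated correlation). Leaving out MFN2-R94Q replicate 2 gave 9 higher cholesterol synthesis genes. Respiratory complex I and complexes II to V had 6 members higher each, of 36 and 39 (13 and 8 adjusted over the list alone, camera adjusted p = 0.00049 and 0.0016, adjusted p = 0.48 and 0.52 with an estimated correlation). Without MFN2-R94Q replicate 2, 1 complex I gene and 2 genes of complexes II to V were higher, and under quantile normalization 2 and 3 were higher and 1 each lower. Neither respiratory list passed after the correction for transcript length and GC content (adjusted p = 0.32 and 0.36), which brought their medians from 0.09 and 0.07 to 0.02 each. Smaller sets of members rose among ependymal markers (4 of 18, among them Foxj1, 6 adjusted over the list alone, camera adjusted p = 0.0098, adjusted p = 0.30 with an estimated correlation). The same held for heat shock genes (2 of 14, Cryab and Bag3, 2 adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.52 with an estimated correlation). Of 13 inhibitory neuron markers 2 fell, among them Gad2 (4 adjusted over the list alone, camera adjusted p = 0.020, adjusted p = 0.16 with an estimated correlation). Without MFN2-R94Q replicate 3 the ependymal, heat shock and inhibitory neuron lists did not pass, at medians of 0.17, 0.12 and -0.08, and the heat shock list also did not pass without MFN2-R94Q:MFN1 replicate 1, at 0.11.

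In all, 1848 genes differed, 1370 higher and 478 lower (74.1% higher); quantile normalization gave 1004 higher and 833 lower (54.7% higher). The groups did not overlap for 20.1% of tested genes, where chance gives 3.57%, and 11 genes changed by 2-fold or more. The count was 882 without MFN2-R94Q replicate 2, 1097 and 1149 without MFN2-R94Q:MFN1 replicates 2 and 5, and 3378 with library weights.

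The third comparison asked what differed from control with both transgenes present, MFN2-R94Q:MFN1 against nTg. Of the 332 genes called, 136 were also called in MFN2-R94Q against nTg, so the rest are not known to be left over from MFN2-R94Q. No group had MFN1 alone, so effects of MFN1 by itself cannot be told apart from those of both transgenes. The list scores of microglial, complement and reactive astrocyte genes were higher in each of the 5 MFN2-R94Q:MFN1 libraries than in any nTg library, and Vps35 was the leading fall. Lgals3 rose 3.95-fold, to 7.95 ± 0.74 RPKM (SD, n = 5) from 1.64 ± 0.094 (n = 3, log2 1.98, SE 0.084, adjusted p = 7.6e-08). Sprr1a rose a fitted 3.77-fold to 1.88 ± 0.87 RPKM, which understates its rise from a low nTg level. C4b rose 2.62-fold, from 20.7 ± 1.9 to 54.9 ± 5.1 RPKM. Vps35, the core subunit of the retromer that recycles endosomal cargo, fell to 0.624 of the nTg level, from 49.3 ± 1.6 to 30.6 ± 0.92 RPKM (log2 -0.68, SE 0.044, adjusted p = 2.2e-06).

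Other leading rises were the lysozyme gene Lyz2 (3.00-fold), Cst7 (2.96-fold), Wisp2 (2.67-fold), the pattern receptor gene Clec7a (2.63-fold), Vim (2.41-fold), Itgax (2.35-fold) and Gpnmb (2.23-fold). The other leading falls were smaller: Plac9a to 0.696 of the nTg level, Egr3 to 0.699, Igfbp2 to 0.713, Creld2 to 0.757, Npas2 to 0.801, Etv5 to 0.807, Arntl to 0.818, Kcnk12 to 0.824 and Sppl2b to 0.832. Of these falls, Vps35 and Npas2 passed the threshold whichever library was left out, and each of the others was lost without at least 1 library. C4b and Plac9a have close copies in the genome, so reads may be divided between copies.

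Vps35 lies on chromosome 8 from 85260392 to 85299802 (GRCm38, minus strand). Its level in MFN2-R94Q, 47.1 ± 3.4 RPKM, did not differ from nTg past the threshold (adjusted p = 0.35), and it was lower in MFN2-R94Q:MFN1 than in MFN2-R94Q as well (0.654 of that level, adjusted p = 2.4e-05). Its partners in the retromer did not pass against nTg: Vps26a had a log2 fold change of 0.06, Vps26b of -0.01 and Vps29 of 0.02. Of 37 tested genes within 1 Mb of Vps35, 1 passed, Man2b1, which was higher by 0.25 on the log2 scale.

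**Figure D3:**
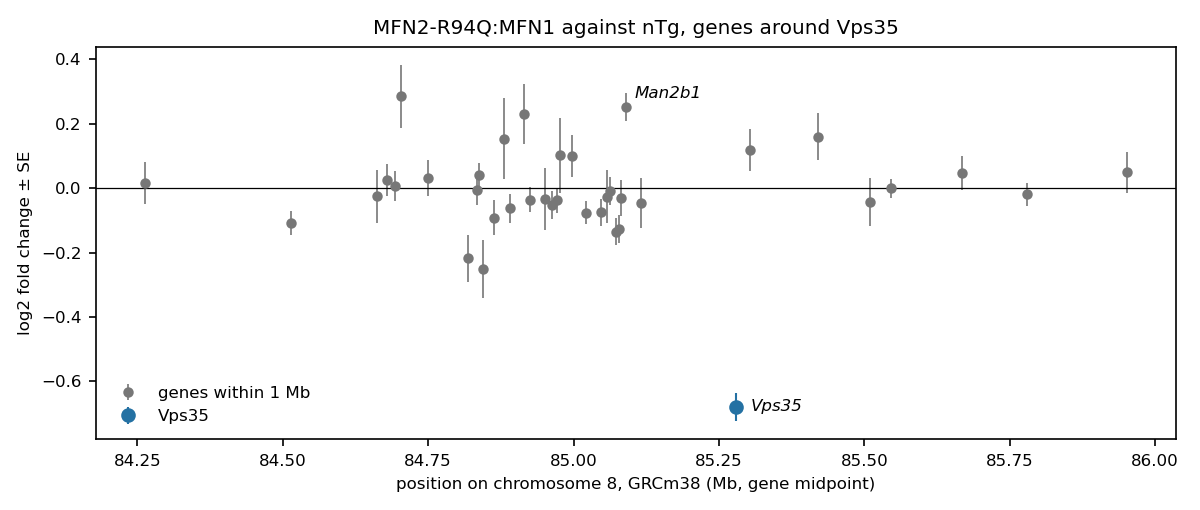
Log2 fold change with its SE (vertical) of Vps35 and the 37 tested genes within 1 Mb of it, MFN2-R94Q:MFN1 against nTg, at each gene's midpoint on chromosome 8 of GRCm38 (horizontal, Mb). Vps35 lies at -0.68, and the median of its neighbours is -0.02.

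Of 29 disease associated microglia genes 24 rose and none fell (26 adjusted over the list alone, camera adjusted p = 2.4e-47, adjusted p = 0.00021 with an estimated correlation). Of 26 microglia markers 15 rose (20 adjusted over the list alone, camera adjusted p = 4.5e-30, adjusted p = 0.020 with an estimated correlation), including Tyrobp at 1.69-fold, Trem2 at 1.69-fold and Ctss at 1.68-fold. Of 33 reactive astrocyte genes 19 rose (25 adjusted over the list alone, camera adjusted p = 3.6e-26, adjusted p = 0.013 with an estimated correlation), with Gfap at 1.70-fold. Of 16 complement genes 11 rose, including C3 at 2.02-fold (13 adjusted over the list alone, camera adjusted p = 7.5e-19, adjusted p = 0.015 with an estimated correlation). Of 22 antigen presentation genes 8 rose, with B2m and H2-K1 at 1.43-fold each (15 adjusted over the list alone, camera adjusted p = 7.4e-11, adjusted p = 0.12 with an estimated correlation). Under quantile normalization 5 antigen presentation genes rose. Of 30 interferon response genes 6 rose, with Ifitm3 at 1.31-fold (13 adjusted over the list alone, camera adjusted p = 2.5e-11, adjusted p = 0.14 with an estimated correlation). Of 18 circadian genes 6 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 7.5e-05, adjusted p = 0.015 with an estimated correlation). Dbp rose 1.69-fold, whereas Npas2 and Arntl fell. A difference in the hour of collection stays open for these clock genes.

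No member of the glucocorticoid list passed against nTg (none adjusted over the list alone, camera adjusted p = 0.98; median log2 0.05, with a camera direction of down, and median -0.01 under quantile normalization). When MFN2-R94Q replicate 2 was left out, 2 glucocorticoid genes were higher and 1 lower, 3 myelin genes were higher and 1 lower, and 4 neurofilament genes were lower. For cholesterol synthesis 1 of 24 genes was lower (1 adjusted over the list alone, camera adjusted p = 0.26), and for myelin 1 of 28 was higher, Tspan2 (2 adjusted over the list alone, camera adjusted p = 0.48). Motor neuron markers kept 1 member lower, Mmp9 at 0.841, and 1 higher, Calca at 1.32-fold (1 and 1 adjusted over the list alone, camera adjusted p = 0.0088, adjusted p = 0.37 with an estimated correlation). The meningeal list had 3 of 17 higher, among them Aebp1 (4 adjusted over the list alone, camera adjusted p = 0.0063, adjusted p = 0.44 with an estimated correlation). Heat shock and cytosolic ribosomal genes had 1 member higher each, Hspb8 and Rpl14, of 14 and 37 (1 each adjusted over the list alone, camera adjusted p = 0.0041 downward and 0.0063 upward, adjusted p = 0.41 and 0.60 with an estimated correlation). Immediate early genes had 1 of 19 lower, Egr3 (1 adjusted over the list alone, camera adjusted p = 0.0063, adjusted p = 0.41 with an estimated correlation). Several further lists passed camera with no member past the threshold over all genes. These were the downward respiratory complexes II to V (median log2 -0.07, none adjusted over the list alone, camera adjusted p = 5.1e-08, adjusted p = 0.28 with an estimated correlation) and complex I (-0.06, none adjusted over the list alone, camera adjusted p = 3.1e-06, adjusted p = 0.35 with an estimated correlation). Also downward were the neurofilament list (-0.06, 1 adjusted over the list alone, camera adjusted p = 2.4e-06, adjusted p = 0.26 with an estimated correlation), general neuronal markers (-0.05, none adjusted over the list alone, camera adjusted p = 0.0041, adjusted p = 0.25 with an estimated correlation) and sensory ganglion markers (-0.09, none adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.25 with an estimated correlation). Pericyte and smooth muscle markers moved upward (0.13, 5 adjusted over the list alone, camera adjusted p = 0.0088, adjusted p = 0.25 with an estimated correlation). Leaving out 1 library ended some of these calls: the ribosomal, immediate early and sensory ganglion lists without nTg replicate 3, at medians of 0.03, -0.09 and -0.08, and the pericyte list without nTg replicate 1, at 0.12. The ribosomal list was also lost without MFN2-R94Q:MFN1 replicate 2, at 0.02, and the meningeal list without MFN2-R94Q:MFN1 replicate 3, at 0.11.

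In all, 332 genes differed, 300 higher and 32 lower, 15 of them by 2-fold or more and all of those higher. The groups did not overlap for 14.1% of tested genes, where chance gives 3.57%. The count was 189, 192 and 213 without nTg replicates 1, 2 and 3, 205 without MFN2-R94Q:MFN1 replicate 4, and 589 without MFN2-R94Q replicate 2, a library outside the comparison.

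The series title concerns the balance of mitofusins, so the last question was how far the MFN2-R94Q changes remained when MFN1 was added. Of the 2561 genes called in MFN2-R94Q against nTg, 136 were also called in MFN2-R94Q:MFN1 against nTg. Lgals3, C4b, Vim, Gfap, Sprr1a, Cst7, Itgax and Gpnmb were called in both. Lgals3, C4b, Cst7 and Gpnmb were among those higher in MFN2-R94Q:MFN1 than in MFN2-R94Q as well (adjusted p = 0.0013 for Lgals3, 0.0096 for C4b and 0.00066 for Cst7). Adjusted over those 2561 genes alone, 1740 (67.9%) differed in the opposite direction in MFN2-R94Q:MFN1 against MFN2-R94Q and 34 in the same direction. Adjusted over all genes, 1107 differed in the opposite direction and 25 in the same direction. In simulated data, 97.4% differed oppositely when MFN1 returned every change to the nTg level, and 0.34 genes did so when MFN1 had no effect. These genes were chosen on the same MFN2-R94Q libraries, so the count is not independent evidence. It was 968 without nTg replicate 2 and 1024 without MFN2-R94Q replicate 2, and the 136 became 71 and 61 without nTg replicates 1 and 2, 89 and 85 without MFN2-R94Q:MFN1 replicates 3 and 4, and 233 without MFN2-R94Q replicate 2. The mean lay closer to nTg with MFN1 for 96.6% of the genes, against 57.9% in simulated data with no effect of MFN1. The simulated genes were drawn independently, so those data hold no shift shared by many genes of a library. MFN2-R94Q replicate 2 lay apart in that way, so the simulated values are not exact references for the real counts.

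Both transgenic groups were compared with the same nTg libraries, which links their values. The 2 sets of calls shared 111 genes that were higher, where independent lists would share 22.5, and 23 that were lower, where independent lists would share 3.31. Across genes, which are not independent replicates, the correlation of the 2 sets of log2 fold changes was 0.52, against 0.55 simulated with no effect. Their covariance was 0.0125, against 0.0041 simulated. The 3 nTg libraries were not split between the comparisons. The simulated covariance already includes the sharing of controls, but for genes drawn independently. It holds no shift shared by many genes of an nTg library, so part of the excess may still come from the shared controls.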

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

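The tests below were chosen after the results they bear on were seen, except the counts of lists over other splits of the libraries.

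In MFN2-R94Q:MFN1, the group of 5, a single library lay far from the others for 19 of 285 values (6.67%), where chance gives about 1 in 20. The values are the gap to the nearest library as a share of the group's range. Single libraries lay above the rest for Wisp2 (0.769), Kcnk12 (0.713), Hspd1 (0.748), Prph (0.905), Olig1 (0.726), Mthfd2 (0.810), C1qc (0.726), Fmod (0.774) and Bhlhe40 (0.713), and for the meningeal list score (0.933, replicate 3). Single libraries lay below the rest for Gpnmb (0.719), Hspa9 (0.810), Fdft1 (0.777), Dhcr7 (0.726), Tef (0.748), Ddit4 (0.721), Kif1a (0.797) and B2m (0.738), and for the sensory ganglion list score (0.736, replicate 4). Replicates 1 to 5 were the outlying library in 4, 6, 4, 4 and 1 cases.

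Other splits of the libraries into groups of the same sizes tested whether chance alone gives as many calls. For MFN2-R94Q:MFN1 against MFN2-R94Q, 1 of 56 splits, the real one, called as many genes (1848, with at most 1 in any other split). That share is under 0.05, which argues against chance but does not exclude it. The same held against nTg, where 1 of 56 splits called as many (332, with at most 2 in any other). For MFN2-R94Q against nTg the 10 splits are too few for a share under 0.05: the real split called 2561 genes and the highest other 0, so 1 of the 10 called as many.

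The counts of gene lists past camera with the preset correlation fared worse. For MFN2-R94Q:MFN1 against MFN2-R94Q, 13 of 56 splits called as many lists as the 14 of the real split, and the highest other called 19, so chance cannot be excluded for that count. Against nTg, 2 of 56 splits called as many as the real 18, a share under 0.05, but the other of those splits called 18 too, so the real count does not stand above the rest. For MFN2-R94Q against nTg the 10 splits are too few: 3 called as many as the real 14, and the highest other called 17. A median of 9 to 11 lists passed in the other splits, so a list call with the preset correlation is weak evidence here.

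Glucocorticoid response genes were higher in MFN2-R94Q than in nTg. Both MFN2-R94Q libraries other than replicate 2, at scores of 0.369 and 0.786, lay above the remaining 8, whose highest score was 0.262. This argues against replicate 2 as the only source, but it rests on those libraries alone. Without replicate 2 the list median was 0.369 (camera adjusted p = 6.51e-07 with the preset correlation). Neither fry nor an estimated correlation was run without replicate 2. With all libraries the list did not pass with an estimated correlation (adjusted p = 0.42) or with fry (adjusted p = 0.054). Transcript length and GC content do not account for the rise either, since the median was 0.872 after their correction. The hour of collection stays open: clock output genes minus Arntl, Npas2 and Clock were 0.265 higher in MFN2-R94Q than in nTg (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The same measure was 0.489 higher in MFN2-R94Q:MFN1 (exact permutation p = 0.0179, the smallest that 3 against 5 libraries can give), where no glucocorticoid gene passed. Whether the genotype or the handling of the mice raised these genes was not tested.

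Disease associated microglia genes were higher in MFN2-R94Q:MFN1 than in nTg, and an effect of the genotype on microglia stays open, untested. The list median was 0.491 after the correction for transcript length and GC content, which argues against that cause. More microglia with no other change would raise the general markers as much, but the disease associated genes rose by 0.271 more on the log2 scale (2-sided exact permutation p = 0.0179, shared members left out). That p is the smallest that 3 against 5 libraries can give. For blood left in the tissue, the group means did not decide, since the rise exceeded that of 7 blood markers by 0.686 with an exact permutation p of 0.125. Of the 5, 3 lay below every nTg library for blood markers yet above each for the microglia genes. In those 3 the rise came with lower blood markers than in any nTg library. The count and its threshold were chosen after that test, with the scores known, so they do not decide the question for the group. Replicate 5 had the highest blood score of all libraries (0.985). The 7 blood markers were globin genes and Alas2, so white blood cells were not assessed.

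Vps35 was lower in MFN2-R94Q:MFN1 than in nTg. Loss or silencing of the region does not account for it, since the median of 37 neighbours within 1 Mb was -0.0193 (SD 0.116). The fall was -0.727 on the log2 scale after the correction for length and GC content. Complete loss of 1 of the 2 copies with no compensation would give 0.5 of the nTg level, below the 0.624 observed (95% interval 0.584 to 0.666). A partial or compensated disruption of the gene, as at a transgene insertion, may account for it and was not tested.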

How the results depend on the processing

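The length and GC correction, and the counts of list members given without MFN2-R94Q replicate 2, were chosen after seeing the data. The other alternatives, with each library left out in turn, were planned. No gene or list past the threshold that the text names reversed its direction. Values near 0 that had not passed changed sign under some settings, among them Mfn2 in MFN2-R94Q and Mfn1 in MFN2-R94Q:MFN1 against nTg. Of the 19, 19 and 20 leading genes named per comparison, 16, 13 and 12 stayed past the threshold whichever library was left out (MFN2-R94Q against nTg, MFN2-R94Q:MFN1 against MFN2-R94Q, and MFN2-R94Q:MFN1 against nTg), as did 11 of 14, 10 of 14 and 13 of 18 lists. In that order, an absolute log2 fold change of at least 1 left 28, 11 and 15 genes, and an adjusted p under 0.1 gave 3927, 3009 and 514, as those thresholds are stricter and looser. A 2-group fit gave 844 genes for the first comparison and 565 for the last, against 2561 and 332 in the fit of all 11 libraries. The 2-group fit differs only in taking the spread without the group outside the comparison, so those counts depend on that pooling. The cause of the following shifts was not tested. No filter gave 1198 for MFN2-R94Q:MFN1 against MFN2-R94Q. Library weights, whose estimation did not converge, gave 3378 there and 590 for MFN2-R94Q:MFN1 against nTg. An estimated correlation left 0, 1 and 5 lists, and fry called 13, 12 and 9, where camera with the preset correlation called 14, 14 and 18. Under quantile normalization Mfn1 passed in MFN2-R94Q against nTg (log2 0.11). The covariance of the relation was 0.0193 and 0.00942 with pseudocounts of 0.1 and 1. Leaving out 1 library gave 1213 to 2857, 882 to 2217 and 189 to 589 genes. It gave correlations of 0.47 to 0.58, covariances of 0.0116 to 0.0151, 61 to 233 genes called in both transgenic groups and 968 to 2157 opposite changes. The sex term was not run, as a single sex was present. How depth limits precision was not tested.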

Other observations

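Endothelial genes went both ways in MFN2-R94Q against nTg, and the list did not pass (camera adjusted p = 0.067), although it did, downward, under quantile normalization (adjusted p = 0.040) and without MFN2-R94Q replicate 2 (adjusted p = 0.043). It did not pass after the correction for transcript length and GC content (adjusted p = 0.065), nor over all libraries with an estimated correlation (adjusted p = 0.47). Of 19 members 8 fell, among them the tight junction gene Cldn5 (to 0.652 of the nTg level) and the receptor gene Kdr (to 0.668), and 3 rose, Slco1a4, Abcb1a and Vwf. Without MFN2-R94Q replicate 2, 6 members fell and 1 rose. With MFN1 added, 7 of the 19 were higher than in MFN2-R94Q, among them Kdr (1.43-fold) and Pltp (1.48-fold), and 2 were without MFN2-R94Q replicate 2. Oligodendrocyte precursor markers were mixed in MFN2-R94Q as well: Olig1 and Olig2 fell to 0.735 and 0.650, whereas Vcan rose 1.26-fold, and the list did not pass (camera adjusted p = 0.23).

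The axon injury list did not pass in any comparison, but single members did. Atf3, a transcription factor induced by nerve injury, rose against nTg by 0.42 on the log2 scale in MFN2-R94Q and by 0.59 in MFN2-R94Q:MFN1, while Tubb2b fell to 0.694 in MFN2-R94Q and was 1.44-fold higher with MFN1. The integrated stress response list did not pass either. In MFN2-R94Q against nTg its adjusted p was 0.039 after the correction for transcript length and GC content, 0.059 under quantile normalization, 0.43 without MFN2-R94Q replicate 2 (1 member higher, against 5) and 0.58 with an estimated correlation. Its member Nupr1 rose 1.68-fold in MFN2-R94Q and 1.48-fold in MFN2-R94Q:MFN1 against nTg. The 7 blood markers did not pass in any comparison; their score ranged from -1.01 in MFN2-R94Q replicate 2 to 0.98 in MFN2-R94Q:MFN1 replicate 5. These genes and lists were picked after their values were seen.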
